A study of Mus musculus with 8 samples.

How the data were processed

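The series holds RNA sequencing of 8 libraries from mouse lung adenocarcinoma cell lines, grouped by their titles into shControl, shNkx2-1, triple knockdown (shRNAs against Nkx2-1, Foxa2 and Cdx2) and Tmet, with 2 libraries each. The labels' protocols give DMEM with 10% serum as the medium, a column kit for RNA, Illumina TruSeq libraries from polyadenylated RNA and single-end reads of 45 nt. The shRNAs were delivered by retroviral or lentiviral vectors, per the labels' protocols. The submitters' processing notes name Bowtie 1.0.1, RSEM 1.2.12 and the genome build mm9, without saying what each did. The authors deposited a table of estimated counts (RSEM expected counts) for 23224 genes, with 34.7% to 38% of a library's values not whole. The gene annotation, read filters and strand setting are not given in the sources used here. Because RSEM divides reads among genes that share sequence, values of near-identical genes (Amd1 and Amd2, Prl2c, Klra and Cyp4a members) are uncertain. The columns of the deposited table name each group by a short form and a replicate number, and the form for the triple knockdown is made of the initials of its 3 targets. All columns matched a sample, and no row lacked a gene name. Of the gene symbols, 20649 matched a RefSeq symbol of the assembly GRCm38.p6 and 2381 matched only a synonym. As that is another build, no coordinates are printed. Only the chromosome of a gene and the gene order along it were taken from that assembly, for the chromosome tests.

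Total estimated counts were 14496995 to 21044835 per library, and levels are in counts-per-million (CPM) with TMM factors applied. TMM factors were 0.943 to 1.035, and the 10 most abundant genes took 4.72% to 5.61% of a library. A floor of 3 counts per library set the lower bound of any fold against a group with no counts. Where a group held 1 to 3 counts, the ratio has a 95% exact counting interval; intervals and floors cover counting error only.

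The estimated counts were rounded to whole numbers. Analyses ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's filterByExpr on the groups (minimum count 10, minimum total 15), leaving 13318 tested and 9906 not tested. All 8 libraries entered 1 edgeR quasi-likelihood fit with TMM factors and no covariate, so that the 4 groups shared 1 estimate of the spread (4 residual degrees of freedom, prior degrees of freedom 3.94, common biological coefficient of variation 15.6%). The 5 contrasts were shNkx2-1, triple knockdown and Tmet each against shControl, triple knockdown against shNkx2-1, and Tmet against triple knockdown. Tests were two-sided, with Benjamini-Hochberg adjustment over the tested genes of a contrast and a threshold of 0.05. The test, the samples in the fit, the gene lists, the rule for named genes and all alternatives but those marked as added were chosen before the data were examined.

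The rule for named genes had 3 parts. The targeted genes, Trp53, Hmga2, Sh3pxd2a, Foxa1, Foxa3, Cdx1, Hnf4a, Cdh1, Vim, Spp1, Sftpb and Sftpc were named whatever their result. For triple knockdown and Tmet against shControl the 8 largest rises and 8 largest falls were picked, and for the other contrasts the 5 largest of each, among genes past the threshold whose groups did not overlap, with at least 5 CPM in the higher group and no predicted or clone name. From each list up to 4 members with the smallest p were taken, of which the text names those ranked first. Some genes that the rule picked are left out of the text. Genes named outside the rule are said to have been chosen after their values were seen.

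The 25 lists (545 genes), fixed from general knowledge, covered alveolar type 2, alveolar type 1, airway, stomach and intestine, liver and plasma protein, epithelial adhesion, mesenchymal, oncofetal, invadopodia and matrix proteolysis, extracellular matrix, cell cycle, hypoxia and glycolysis, interferon, inflammatory, RAS-ERK feedback, TGF-beta and YAP, Wnt, p53 target, leukocyte, endothelial, fibroblast, neuroendocrine and sex-linked genes, the label check genes, and relatives of the targeted genes. Lists with at least 5 tested members were tested with limma's camera on the edgeR object with a preset correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry were alternatives. Members were counted over all genes tested and adjusted over the list alone. A list's median was also taken with each gene that had 0 counts in 1 group at its bound and each gene at or under the floor in both groups at 0.

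Shared calls were set against the number that independent lists of the same sizes would share, with Fisher's exact test per direction. For the contrasts that share shControl, 100 simulations drew the control and both compared groups, with 2 libraries each, from the shControl means. Each gene had the spread estimated over all 8 libraries. These simulations gave the correlation, covariance and shared calls that shared controls produce alone. The procedure was tested on counts simulated for all 8 libraries. The triple knockdown means were those of shControl, with 200 genes changed by known factors. The spread of each gene was that estimated over all 8 libraries, Tmet included. Among 13100 genes, 8 of 125 calls (6.4%) were false and no call had the wrong direction. All groups thus had the same spread, which the real duplicates did not, and far fewer genes changed than were called in the data.

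The alternatives were DESeq2 size factors, no low-count filter, a filter of 5 CPM in 2 libraries, a fit of the 4 libraries compared, the replicate number as a block, DESeq2's Wald test, limma-voom, counts not rounded, glmTreat against a 2-fold change, and leaving out each library in turn. A fit without both Tmet libraries, and all alternatives for the calls shared by the contrasts against shControl, were added after seeing the data. A fit that leaves out 1 library keeps 1 library in its group, which is then assumed to vary like the other groups. No library was left out of the reported fit. The multidimensional scaling used the 500 leading genes per pair of libraries, and correlations between libraries or groups were taken on log2(CPM + 1).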

Results

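Polyadenylated RNA from mouse lung adenocarcinoma cell lines was sequenced in 8 libraries, which fall into 4 groups of 2. All lines lacked Trp53, per the labels. Tnonmet lines came from a primary tumour that had not metastasised and carried either a control shRNA against luciferase (shControl), an shRNA against Nkx2-1 (shNkx2-1), or shRNAs against Nkx2-1, Foxa2 and Cdx2 together (called the triple knockdown here). Tmet lines came from a primary tumour that had metastasised, and no shRNA is named for them. Nkx2-1 is a homeobox transcription factor of the lung lineage, Foxa2 a forkhead factor of endoderm, and Cdx2 a homeobox factor of the intestine. The series title names the question: whether Foxa2 and Cdx2 act together with Nkx2-1 in restraining metastasis. Total estimated counts were 14496995 and 18918538 in the shControl libraries, 16203758 and 17599131 in shNkx2-1, 16830021 and 15953814 in the triple knockdown, and 18093561 and 21044835 in Tmet. Each library had counts for 15198 to 15978 of the 23224 genes listed, and a floor of 3 counts stood at 0.151 to 0.2 CPM (counts-per-million). Levels are given as mean CPM ± SD over the 2 libraries of a group (n = 2), fold changes as log2 values ± SE, and adjusted p-values are those of edgeR's quasi-likelihood test over 13318 genes. Nothing states that the duplicates were separate cultures, so the p-values measure the spread between duplicates, which may be technical. Counting intervals and floors cover counting error only, because PCR copies of a molecule were not marked.

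The targeted genes were lower in the groups named for them, to unequal extents. Nkx2-1 stood at 76.4 and 68.0 CPM in the shControl libraries, 37.7 and 44.8 in shNkx2-1, 38.1 and 34.0 in the triple knockdown, and 0.219 and 0.353 in Tmet, where the counts were 4 and 7. Foxa2 stood at 56.8 and 55.1 CPM in shControl, 49.2 and 41.6 in shNkx2-1, 34.1 and 28.2 in the triple knockdown, and 1.2 and 1.36 in Tmet. Cdx2 stood at 98.6 and 111 CPM in shControl, 175 and 186 in shNkx2-1, 9.41 and 6.80 in the triple knockdown, and 0.383 and 0.353 in Tmet. Against shControl, Nkx2-1 fell in shNkx2-1 (log2 change -0.81 ± 0.15, adjusted p = 0.0318) and in the triple knockdown (-1.0 ± 0.15, adjusted p = 0.00273). Foxa2 fell in the triple knockdown (-0.84 ± 0.15, adjusted p = 0.00519), and Cdx2 fell there more (-3.69 ± 0.17, adjusted p = 1.59e-05). In Tmet the 3 genes were lower by -7.93 ± 0.24, -5.44 ± 0.20 and -8.13 ± 0.24 on the log2 scale, with adjusted p-values of 3.33e-07, 5.71e-07 and 3.02e-07. The fall of Nkx2-1 in shNkx2-1 lost its call in 6 of the 8 fits that left out 1 library, namely those without either shControl, shNkx2-1 or triple knockdown library, with adjusted p from 0.00351 to 0.286 over the 8 fits. The fall of Foxa2 in the triple knockdown lost its call without triple knockdown replicate 2 (adjusted p = 0.0578). Trp53 stood at 4.67 ± 0.183 CPM in shControl, 5.50 ± 1.08 in shNkx2-1, 3.78 ± 0.451 in the triple knockdown and 8.93 ± 1.27 in Tmet, and since the part of Trp53 that was deleted is not given in the sources used here, its level does not check the genotype.

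**Figure D1:**
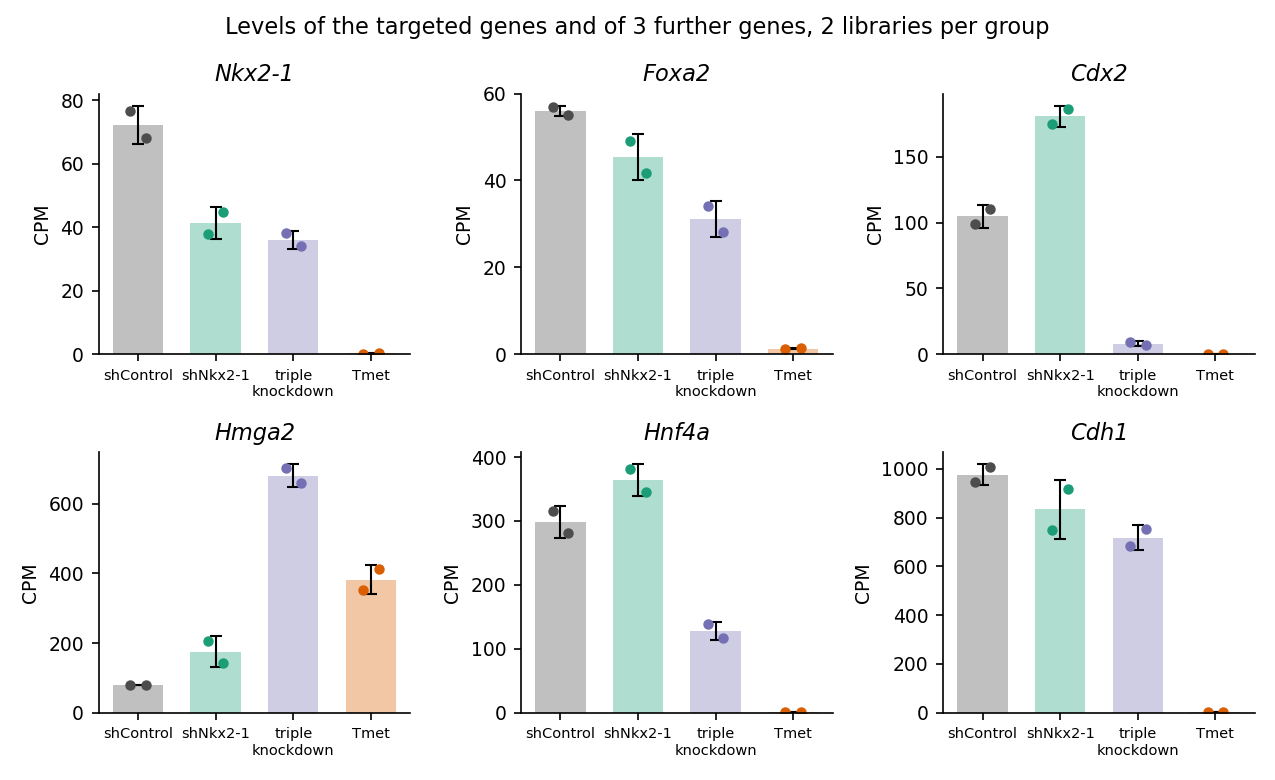
Level in CPM (y axis, from 0) of the 3 targeted genes and of Hmga2, Hnf4a and Cdh1 in the 4 groups (x axis); points are libraries, bars the mean of 2 libraries and error bars the SD. Cdx2 averaged 105 CPM in shControl, 181 in shNkx2-1, 8.10 in the triple knockdown and 0.368 in Tmet, and Hmga2 was highest in the triple knockdown, at 680 CPM.

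Tmet stood apart from the 3 Tnonmet groups. In a multidimensional scaling of the 500 most variable genes per pair of libraries, the first dimension held 68.0% of the variance and placed the Tmet libraries at 4.39 and 4.37, the triple knockdown at -0.62 and -0.69, and the other 4 libraries between -1.95 and -1.71. Across genes, which are not independent replicates, group means of log2 CPM correlated at r = 0.986 between shNkx2-1 and shControl, 0.953 between the triple knockdown and shControl, and 0.839 between Tmet and shControl. The triple knockdown correlated with Tmet at 0.882, and shNkx2-1 with Tmet at 0.840. Duplicates correlated at 0.994 to 0.996 in the Tnonmet groups and at 0.978 in Tmet, whose libraries differed most: the chi-square per gene over genes with at least 10 counts was 66.9 in Tmet and 8.61 to 13.2 in the others, above the sampling noise in every group.

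**Figure D2:**
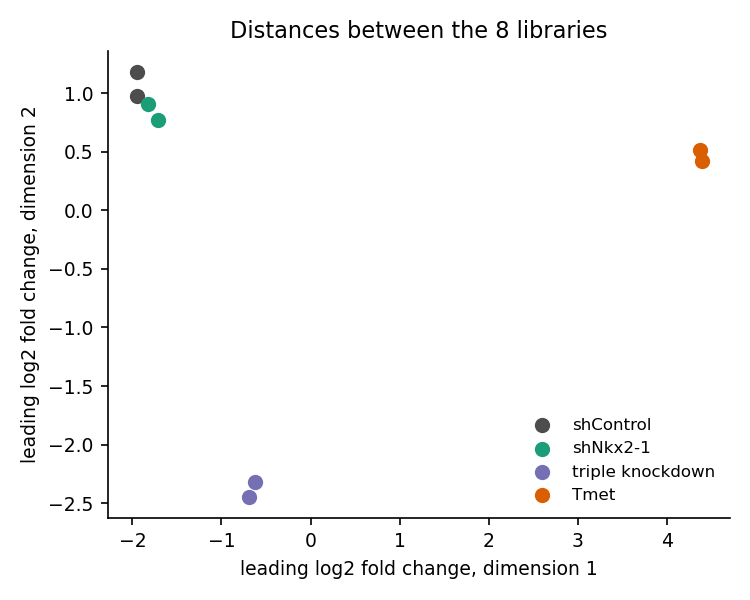
Multidimensional scaling of the 8 libraries, each point 1 library coloured by group; the axes are leading log2 fold changes, with 68.0% of the variance on dimension 1 and 19.9% on dimension 2. Tmet lies at 4.37 and 4.39 on dimension 1, and the triple knockdown at -2.32 and -2.44 on dimension 2.

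The comparison of shNkx2-1 with shControl asks what the Nkx2-1 shRNA alone changed in Tnonmet cells. Cdx2 rose (log2 change 0.79 ± 0.15, adjusted p = 0.0328), as did Hmga2, an architectural chromatin protein of embryonic tissues, from 79.4 ± 1.21 to 175 ± 44.9 CPM (1.14 ± 0.17, adjusted p = 0.0176). The RNA-binding protein gene Igf2bp2 rose from 6.81 ± 0.295 to 66.6 ± 16.6 CPM (3.29 ± 0.25, adjusted p = 0.00333). Tmem151a rose from 0.561 ± 0.228 to 5.77 ± 0.433 CPM (3.31 ± 0.32, adjusted p = 0.00456). The iron exporter gene Slc40a1 rose from 7.45 ± 1.63 to 58.2 ± 9.85 CPM (2.97 ± 0.33, adjusted p = 0.00764). Ugt2b34, a glucuronosyltransferase gene, rose by 3.21 ± 0.33 and C4bp, a regulator of complement, by 3.0 ± 0.33 on the log2 scale (adjusted p = 0.0057 and 0.00625). Krt20, a keratin of gut epithelium, fell from 161 ± 20.5 to 9.11 ± 0.694 CPM (-4.15 ± 0.64, adjusted p = 0.0181), and Oit1, Pla1a and Cd34 changed by -4.80 ± 0.49, -4.29 ± 0.45 and -4.11 ± 0.47 (adjusted p = 0.0057, 0.00586 and 0.00764). Amd1, an enzyme of polyamine synthesis with a near-identical copy, Amd2, had 352 estimated counts in each shControl library, although their totals differ, and 0 in both shNkx2-1 libraries. Its call here (adjusted p = 0.0057) is not read as a change in level, since its counts did not follow the totals and reads can be split between the copies. Foxa2 (-0.30 ± 0.15, adjusted p = 0.321), Foxa1 (-0.02, adjusted p = 0.955), Hnf4a (0.29, adjusted p = 0.329), Cdh1 (-0.23, adjusted p = 0.385), Vim (0.20, adjusted p = 0.395), Sh3pxd2a (0.23, adjusted p = 0.454) and Trp53 (0.23, adjusted p = 0.687) did not pass. Nor did Spp1 (-1.71 ± 0.43, adjusted p = 0.0766), which did by DESeq2 (adjusted p = 0.0338). Sftpb averaged 0.527 CPM in shNkx2-1 and 0.710 in shControl, Sftpc was at or under the floor in both groups, and Cdx1 had 0 counts in all 8 libraries.

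Among the lists in this comparison, TGF-beta and YAP targets were called higher by camera (adjusted p = 0.000568), a call lost by camera (adjusted p = 0.584 with an estimated correlation) and by fry (adjusted p = 0.125). Their median log2 change was 0.39, or 0.38 with groups at 0 counts held at their bound, and their mean 0.58. Of 24 tested members 2 rose and 0 fell, against 5 and 0 adjusted over the list alone. Tgfb2, a TGF-beta ligand, rose from 3.63 ± 1.36 to 19.8 ± 6.88 CPM (2.43 ± 0.36, adjusted p = 0.0161). Smad6, an inhibitory SMAD, rose from 7.82 to 19.5 CPM (1.31, adjusted p = 0.0499, but 0.0511 with DESeq2 size factors). Oncofetal genes were also called higher (2 of 16 rose, 0 fell; 5 and 0 adjusted over the list alone), with camera adjusted p = 0.0048 and adjusted p = 0.559 with an estimated correlation. This call was lost by fry (adjusted p = 0.0586) and without shControl replicate 2 or either Tmet library, with adjusted p from 5.85e-05 to 0.249 over the fits that left out 1 library. Among 35 matrix genes 6 rose and 2 fell (10 and 7 adjusted over the list alone), with camera adjusted p = 0.157. Fbln2, a basement membrane fibulin, rose from 113 ± 28.5 to 467 ± 21.1 CPM (2.04 ± 0.20, adjusted p = 0.00456), and Col4a1, a basement membrane collagen, fell from 1028 ± 72.2 to 499 ± 28.7 (-1.04 ± 0.13, adjusted p = 0.00858). Of 24 mesenchymal genes 3 rose and 0 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.157), led by Sparc (0.72 ± 0.10, adjusted p = 0.0127), and of 8 fibroblast genes 1 rose (2 adjusted over the list alone; camera adjusted p = 0.157), Cspg4 (2.71 ± 0.55, adjusted p = 0.0419, but 0.0698 by limma-voom). The actin-bundling Fscn1 rose from 127 ± 23.4 to 302 ± 4.78 CPM (1.25 ± 0.17, adjusted p = 0.0117), and Dsp, a desmosome protein, fell from 259 ± 13.3 to 98.0 ± 17.8 (-1.40 ± 0.19, adjusted p = 0.0114). Stomach and intestine genes split, with 1 of 25 higher and 2 lower (4 and 3 adjusted over the list alone): Lgals2, a galectin of the gut, rose from 38.3 to 124 CPM (adjusted p = 0.00333), while Krt20 and Agr2 fell. Their median was 0.07, their mean -0.14 and the camera direction upward (adjusted p = 0.675). The camera direction also differed from the sign of the median, the mean or both for interferon, inflammatory, RAS-ERK and p53 target genes, none of them past its test.

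The edgeR test called 473 genes between shNkx2-1 and shControl, 289 higher and 184 lower, of which 176 and 100 changed more than 2-fold. Without adjustment 2501 passed p 0.05, and in 58.4% of tested genes the groups did not overlap, where chance gives 33.3%. This count depended on which libraries entered the fit. Fits without 1 Tnonmet library called far fewer genes by edgeR, fewest without shControl replicate 1. Fits without 1 library of Tmet, whose duplicates differed most, called more. A fit with 1 library left in a group cannot tell a change that rests on the library left out from a poorer estimate of the spread. Each gene call named for this comparison was lost without shControl replicate 1. Those of Tmem151a, Igf2bp2, Amd1, Lgals2 and Fbln2 were lost only there, with adjusted p from 0.0649 to 0.07, and the others also without at least 1 other Tnonmet library, with adjusted p up to 0.38. The count was 1779 in a fit of the 4 libraries compared, 2006 without both Tmet libraries and 908 by DESeq2.

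The comparison of the triple knockdown with shControl asks what the 3 shRNAs changed together. Hmga2 rose from 79.4 ± 1.21 to 680 ± 31.8 CPM (log2 change 3.10 ± 0.18, adjusted p = 5.29e-05). Vim, the intermediate filament protein of mesenchymal cells, rose from 2232 ± 58.7 to 4470 ± 387 CPM (1.00 ± 0.11, adjusted p = 0.000756). Hnf4a, a nuclear receptor of liver and gut, fell from 298 ± 24.7 to 128 ± 14.6 CPM (-1.22 ± 0.14, adjusted p = 0.000898). Foxa1, the closest relative of Foxa2, fell from 99.5 ± 0.875 to 32.5 ± 2.02 CPM (-1.61 ± 0.13, adjusted p = 0.000162). The cytochrome P450 gene Cyp4f14 fell from 126 ± 12.6 to 0.618 ± 0.149 CPM (-7.65 ± 0.34, adjusted p = 1.36e-05). Wnt7a, a Wnt ligand, rose from 1.62 ± 0.12 to 96.0 ± 9.59 CPM (5.88 ± 0.47, adjusted p = 0.000172). Lrp2, the endocytic receptor megalin, rose from 2.04 ± 0.62 to 216 ± 93.6 CPM (6.70 ± 0.88, adjusted p = 0.00153).

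Among the other large rises, Slc4a11 reached 37.9 ± 0.29 CPM (6.09 ± 0.40, adjusted p = 7.56e-05), the claudin gene Cldn9 17.8 ± 3.76 (6.06 ± 0.41, adjusted p = 8.69e-05) and Padi1, a peptidylarginine deiminase, 8.47 ± 4.73 (6.09 ± 0.78, adjusted p = 0.00134). Dok7, an adaptor of the muscle kinase MuSK, had 0 counts in shControl and 14 ± 0.871 CPM in the triple knockdown, at least 78.9-fold higher. Ttc9 and Mmp24, a membrane-type metalloproteinase, had 1 to 3 counts in shControl, and their ratios were 103 (95% counting interval 28.0 to 853) and 89.0 (30.1 to 434). Several genes fell to between 1 and 3 counts in the triple knockdown. The ratio of shControl to triple knockdown was 599 (interval 166 to 4954) for Gdf6, a bone morphogenetic protein, 441 (78.8 to 17457) for Otc, a urea cycle enzyme, 355 (63.3 to 14055) for Igfbp5, 327 (58.3 to 12945) for Hs3st5, a heparan sulfate sulfotransferase, and 212 (72.3 to 1032) for Reps2. Amd1 was at 0 again, and is not read as a change here either. Sh3pxd2a, a scaffold of invadopodia, rose from 162 ± 10.5 to 256 ± 25.6 CPM (0.66 ± 0.14, adjusted p = 0.0118). Its call was lost without shControl replicate 1 or 2 or triple knockdown replicate 2, with adjusted p up to 0.102. Cdh1, the epithelial cadherin, fell from 975 ± 42.2 to 718 ± 50.6 CPM (-0.44 ± 0.12, adjusted p = 0.0347). That call was lost without either shControl or either triple knockdown library, with adjusted p up to 0.224. Foxa3 rose from 0.111 to 0.622 CPM (2.36 ± 0.63, adjusted p = 0.0359), a call lost by DESeq2 (adjusted p = 0.304) and in each fit without 1 of the 6 Tnonmet libraries (adjusted p up to 0.25). Spp1 (0.74 ± 0.42, adjusted p = 0.239), Trp53 (-0.30 ± 0.25, adjusted p = 0.418) and Sftpb (0.811 CPM against 0.710, adjusted p = 0.763) did not pass, and Sftpc was at the floor.

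Of 25 tested stomach and intestine genes 16 fell and 1 rose in the triple knockdown (17 and 1 adjusted over the list alone), with a median log2 change of -2.32. The camera test gave adjusted p = 5.61e-23, and adjusted p = 0.064 with an estimated correlation. Lgals4, a galectin of the gut, fell from 838 ± 37.6 to 39.5 ± 1.58 CPM (-4.41 ± 0.12, adjusted p = 1.67e-06). Vil1, the villin of microvilli, fell from 103 ± 21 to 1.24 ± 0.21 CPM (-6.37 ± 0.23, adjusted p = 5.29e-06). Lgals2 fell from 38.3 to 3.64 CPM (-3.39). Of 23 hypoxia and glycolysis genes 14 rose and none fell (17 and 0 adjusted over the list alone; median 0.89; camera adjusted p = 7.34e-07, and adjusted p = 0.0934 with an estimated correlation). Hk2, a hexokinase, rose from 40.7 ± 3.41 to 137 ± 17.6 CPM (1.75 ± 0.15, adjusted p = 0.000235) and Gapdh from 3788 to 6998 (0.89 ± 0.10, adjusted p = 0.000953). Of 32 cell cycle genes 9 rose and none fell (10 and 0 adjusted over the list alone; median 0.41; camera adjusted p = 0.00199, and adjusted p = 0.622 with an estimated correlation; fry adjusted p = 0.127). Cenpe, a mitotic kinesin, rose from 116 ± 1.69 to 187 ± 6.18 CPM (0.69 ± 0.12, adjusted p = 0.0046), a call lost without shControl replicate 1 (adjusted p = 0.0527). Among 17 inflammatory genes 8 rose and 1 fell (9 and 1 adjusted over the list alone; median 1.01; camera adjusted p = 0.00289, and adjusted p = 0.0934 with an estimated correlation). Tnfaip2 rose from 61.4 ± 1.12 to 265 ± 1.90 CPM (2.11 ± 0.16, adjusted p = 0.000137). The chemokine gene Cxcl1 rose from 4.51 to 16.2 CPM (1.85 ± 0.19, adjusted p = 0.000539). RAS-ERK feedback targets had 9 of 21 higher and 1 lower (10 and 1 adjusted over the list alone; median 0.58; camera adjusted p = 0.000959, and adjusted p = 0.221 with an estimated correlation). Epha2, an ephrin receptor, rose from 303 ± 26.4 to 572 ± 48.6 CPM (0.91 ± 0.12, adjusted p = 0.00131). Epha2 was also the stomach and intestine member that rose.

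Of 35 matrix genes 12 rose and 1 fell in the triple knockdown (16 and 3 adjusted over the list alone; median 0.53). Camera gave adjusted p = 6.25e-06, and adjusted p = 0.0934 with an estimated correlation. Fbln2 rose from 113 to 1609 ± 92.5 CPM (3.83 ± 0.21, adjusted p = 3.4e-05). Col5a1 rose from 38.0 to 170 CPM (2.16 ± 0.16, adjusted p = 0.000117). The laminin chain gene Lamb3 rose from 67.5 to 194 CPM (1.52). Of 27 genes of invadopodia and matrix proteolysis 11 rose and 2 fell (13 and 2 adjusted over the list alone; median 0.59, or 0.14 with groups at 0 counts held at their bound; camera adjusted p = 0.0033, and adjusted p = 0.0934 with an estimated correlation). The metalloprotease gene Adam8 rose from 4.57 ± 0.988 to 53.1 ± 0.984 CPM (3.55 ± 0.27, adjusted p = 0.000151), and Fscn1 reached 393 CPM (1.63 ± 0.17, adjusted p = 0.000496). Mesenchymal genes had 7 of 24 higher and 1 lower (8 and 2 adjusted over the list alone; median 0.20, or 0.14 with groups at 0 counts held at their bound; camera adjusted p = 0.081). Snai2, a repressor of epithelial genes, rose from 4.41 to 15.6 ± 1.79 CPM (1.82 ± 0.20, adjusted p = 0.000683). Beside them, the fibroblast list, of which 3 of 16 genes lay over 1 CPM in shControl and 5 in the triple knockdown, had 2 of 8 tested genes higher and 1 lower (4 and 1 adjusted over the list alone; median 1.80, or 0.83 with groups at 0 counts held at their bound; camera adjusted p = 0.435). TGF-beta and YAP targets had 9 of 24 higher and 2 lower (10 and 2 adjusted over the list alone; camera adjusted p = 0.00501, and adjusted p = 0.382 with an estimated correlation). Ankrd1, a YAP target, rose from 87.9 ± 8.51 to 299.9 ± 22.5 CPM (1.77 ± 0.11, adjusted p = 7.4e-05), and Pmepa1 also rose (1.44, adjusted p = 0.00029). Oncofetal genes had 5 of 16 higher and 0 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.0111, and adjusted p = 0.201 with an estimated correlation), led by Hmga2, Igf2bp2 (73.2 ± 17.6 CPM; 3.42 ± 0.25, adjusted p = 0.000126) and Hmga1 (1.75 ± 0.16, adjusted p = 0.000316). Without either Tmet library the list's call was lost (adjusted p up to 0.23).

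Epithelial genes went both ways, with 5 of 29 higher and 10 lower (5 and 11 adjusted over the list alone; median -0.32, mean -0.06; camera adjusted p = 0.793). Krt7, a keratin of simple epithelia, rose from 116 ± 11.1 to 1138 ± 38.7 CPM (3.29 ± 0.15, adjusted p = 1.59e-05). Cldn6 rose from 2.13 to 36.8 CPM (4.06 ± 0.44, adjusted p = 0.000627). Pkp3, a desmosomal plakophilin, rose from 0.229 to 5.02 CPM (4.39, adjusted p = 0.000708). Alveolar type 1 genes had 4 of 12 higher and 1 lower (5 and 1 adjusted over the list alone). Cav1, the caveolin, rose from 126 ± 26.2 to 498 ± 65.5 CPM (1.98 ± 0.17, adjusted p = 0.000235), and Emp2 also rose (1.54, adjusted p = 0.000482). Their median was -0.08, their mean 0.37 and the camera direction upward (adjusted p = 0.031, and adjusted p = 0.382 with an estimated correlation). The call was lost without shControl replicate 1, triple knockdown replicate 2 or either Tmet library (adjusted p from 0.00407 to 0.194). Alveolar type 2 genes had 3 of 12 higher and 3 lower (3 and 4 adjusted over the list alone; median 0.19, mean -0.42, camera direction downward, adjusted p = 0.793). Cebpa, a transcription factor, fell from 9.74 to 0.811 CPM (-3.58 ± 0.38, adjusted p = 0.000558). Of 5 airway genes 1 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.464). Aldh1a1, a retinaldehyde dehydrogenase, fell from 212 ± 51.5 to 22.5 ± 7.77 CPM (-3.24 ± 0.30, adjusted p = 0.000314). Interferon genes had 1 of 26 higher and 3 lower over all genes and over the list alone (camera adjusted p = 0.552), and Wnt target and feedback genes 2 of 9 higher and 2 lower (camera adjusted p = 0.598). Among p53 target genes 4 of 17 were higher and 2 lower (camera adjusted p = 0.296), led by Cdkn1a, a cell cycle inhibitor (1.56 ± 0.15, adjusted p = 0.000417). The label check genes fell as a list (3 of 5 lower, 1 higher; median -0.84; camera adjusted p = 0.00289, and adjusted p = 0.201 with an estimated correlation), a call lost without either Tmet library (adjusted p up to 0.0968). The sex-linked transcripts had 0 of 5 past the test (camera adjusted p = 0.793; edgeR adjusted p over the list alone also called 0). Lists with under 5 tested members were not tested as lists: 1 of 4 liver genes rose and 1 fell (Foxa3 and Apob), and 1 of 2 leukocyte genes rose (Cd14, from 28.9 to 59.9 CPM). In the same way 1 of 4 endothelial genes rose (Egfl7, from 1.78 to 3.58), 1 of 4 neuroendocrine genes fell (Ddc, from 3.66 to 0.933), and 1 of 3 relatives of the targeted genes rose and 1 fell (Foxa3 and Foxa1). Of these calls, that of Apob was lost without shControl replicate 1 or triple knockdown replicate 2 (adjusted p up to 0.153), that of Cd14 without shControl replicate 2 (adjusted p = 0.0507), and those of Foxa3, Egfl7 and Ddc without any of the 6 Tnonmet libraries (adjusted p up to 0.25, 0.212 and 0.246); DESeq2 did not call Egfl7 (adjusted p = 0.114), nor limma-voom Ddc (adjusted p = 0.0683).

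The edgeR test called 3243 genes between the triple knockdown and shControl, 1597 higher and 1646 lower, of which 801 and 865 changed more than 2-fold. Without adjustment 4875 passed p 0.05, and the groups did not overlap in 72.4% of tested genes, where chance gives 33.3%. The count was 1248 and 1576 without shControl replicate 1 or 2, 1461 and 1428 without triple knockdown replicate 1 or 2, 5459 and 5453 without Tmet replicate 1 or 2, 5424 without both Tmet libraries and 5607 in a fit of the 4 libraries compared. On simulated counts for this comparison, the same test recovered 6 of 67 genes changed 1.5-fold, 48 of 67 changed 2-fold and 63 of 66 changed 4-fold, and 8 of its 125 calls were false. Those counts had the same spread in every group and only 200 changed genes.

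The comparison of the triple knockdown with shNkx2-1 asks what the Foxa2 and Cdx2 shRNAs added. Cdx2 fell from 181 ± 7.83 to 8.10 ± 1.85 CPM (log2 change -4.48 ± 0.18, adjusted p = 6.93e-06). Foxa2 fell from 45.4 ± 5.32 to 31.2 ± 4.18 CPM (-0.54 ± 0.15, adjusted p = 0.0355), a call lost in each fit without 1 of the 6 Tnonmet libraries (adjusted p up to 0.239). Nkx2-1 did not pass (-0.20 ± 0.15, adjusted p = 0.404). Clrn3 fell from 37.4 ± 3.98 to 0.126 CPM (-8.15 ± 0.40, adjusted p = 2.07e-05). Gdf6 and Cst9, a cystatin gene, had 1 to 3 counts in the triple knockdown, with ratios of shNkx2-1 to triple knockdown of 660 (95% counting interval 182 to 5452) and 453 (155 to 2197). Cldn9 rose (5.89 ± 0.40, adjusted p = 0.000104). Fam167a rose from 0.202 to 13.7 ± 4.24 CPM (6.02 ± 0.51, adjusted p = 0.000274), and Mtap1a, a microtubule-associated protein gene, had a ratio of 214 (37.9 to 8479) of triple knockdown to shNkx2-1. Hmga2 (1.96 ± 0.18, adjusted p = 0.000342) and Vim (0.80 ± 0.11, adjusted p = 0.00251) rose, and Foxa1 (-1.59 ± 0.13, adjusted p = 0.000197) and Hnf4a (-1.51 ± 0.14, adjusted p = 0.000445) fell. Spp1, the secreted phosphoprotein osteopontin, rose from 383 ± 162 to 2099 ± 674 CPM (2.45 ± 0.44, adjusted p = 0.00682), a call lost without shNkx2-1 replicate 1 (adjusted p = 0.0528). Sh3pxd2a (0.44 ± 0.14, adjusted p = 0.0642; 0.0362 by DESeq2) and Cdh1 (-0.22, adjusted p = 0.259) did not pass. Members of multigene families were uncertain: Prl2c3 had 0 counts in shNkx2-1 and 35.4 ± 12 CPM in the triple knockdown, and Prl2c2 and Cyp4a12a also have close copies.

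Stomach and intestine genes fell here too, 17 of 25 with 1 rising (18 and 2 adjusted over the list alone; median -1.84), with camera adjusted p = 3.13e-27 and adjusted p = 0.0359 with an estimated correlation, so this call held under both. Lgals4 fell from 743 ± 38.7 to 39.5 CPM (-4.23 ± 0.12, adjusted p = 2.16e-06). Lgals2 fell from 124 to 3.64 CPM (-5.09 ± 0.18, adjusted p = 4.62e-06). Vil1 fell from 76.0 to 1.24 CPM (-5.93 ± 0.23, adjusted p = 6.2e-06). Hypoxia and glycolysis genes rose, 17 of 23 with none falling (18 and 1 adjusted over the list alone; median 0.86; camera adjusted p = 4.89e-10, and adjusted p = 0.0801 with an estimated correlation). Hk2 rose from 31.6 to 137 CPM (2.12 ± 0.15, adjusted p = 0.000134). Cell cycle genes had 11 of 32 higher and none lower (23 and 0 adjusted over the list alone; median 0.58; camera adjusted p = 1.03e-06, and adjusted p = 0.649 with an estimated correlation; fry adjusted p = 0.0735), among them Cenpe (0.85 ± 0.12, adjusted p = 0.00238). Inflammatory genes (6 of 17 higher, 0 lower; 7 and 1 adjusted over the list alone; camera adjusted p = 0.000399, and adjusted p = 0.0955 with an estimated correlation) were led by Tnfaip2 (1.73 ± 0.16, adjusted p = 0.000371). The cytokine gene Lif rose from 28.8 to 99.0 CPM (1.78 ± 0.20, adjusted p = 0.000946). RAS-ERK targets (6 of 21 higher, 0 lower; 11 and 0 adjusted over the list alone; camera adjusted p = 0.000277, and adjusted p = 0.228 with an estimated correlation) were led by the phosphatase gene Dusp5 (1.72, adjusted p = 0.00197). Of 35 matrix genes 17 rose and 4 fell (18 and 5 adjusted over the list alone; median 0.75; camera adjusted p = 0.000197, and adjusted p = 0.159 with an estimated correlation). P4ha1, a collagen prolyl hydroxylase, rose from 33.3 to 101 CPM (1.60 ± 0.14, adjusted p = 0.000276), and Thbs1, thrombospondin-1, fell from 1288 ± 678 to 88.1 ± 14.8 (-3.87 ± 0.45, adjusted p = 0.00115). Fibroblast genes (1 of 8 higher, 2 lower; 2 and 3 adjusted over the list alone) had a median of 0.55, or -0.04 with groups at 0 counts held at their bound, a mean of 0.42 and a downward camera direction (adjusted p = 0.95). Invadopodia genes (7 of 27 higher, 2 lower; 9 and 2 adjusted over the list alone; camera adjusted p = 0.0249, and adjusted p = 0.186 with an estimated correlation; call lost without either Tmet library, adjusted p up to 0.0515) were led by Adam8 (2.56 ± 0.26, adjusted p = 0.000552). Alveolar type 1 genes (6 of 12 higher, 1 lower, also adjusted over the list alone; camera adjusted p = 0.0105, and adjusted p = 0.374 with an estimated correlation) were led by Emp2 (1.57, adjusted p = 0.00055). The label check genes were called lower (camera adjusted p = 0.0249, and adjusted p = 0.366 with an estimated correlation), a call lost without either Tmet library (adjusted p up to 0.33). Median, mean and camera direction differed in sign for alveolar type 2, epithelial, mesenchymal, oncofetal, TGF-beta and YAP and sex-linked genes, none of them past its test.

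The edgeR test called 2711 genes in this comparison, 1235 higher and 1476 lower, of which 559 and 849 changed more than 2-fold. Without adjustment 4519 passed p 0.05, and the groups did not overlap in 70.0% of tested genes, where chance gives 33.3%. The count was 1466 and 1027 without shNkx2-1 replicate 1 or 2, 1168 and 1024 without triple knockdown replicate 1 or 2, 4994 and 4984 without Tmet replicate 1 or 2, 4958 without both Tmet libraries and 4518 in a fit of the 4 libraries compared.

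The comparison of Tmet with shControl sets lines from the tumour that metastasised against control-treated lines from the one that had not. Besides the targeted genes, Cdh1 fell from 975 ± 42.2 to 3.25 ± 0.11 CPM (log2 change -8.23 ± 0.18, adjusted p = 1.11e-07). Hnf4a fell from 298 ± 24.7 to 0.727 ± 0.255 CPM (-8.65 ± 0.22, adjusted p = 1.87e-07). Foxa1 fell from 99.5 to 39.8 ± 2.40 CPM (-1.32 ± 0.13, adjusted p = 7.6e-05). Hmga2 rose to 382 ± 41.3 CPM (2.26 ± 0.18, adjusted p = 2.76e-05) and Vim to 5401 ± 338 (1.27 ± 0.11, adjusted p = 5.28e-05). Several genes had 0 counts in shControl and were higher in Tmet by at least 126-fold (Apbb1ip, 22.3 ± 4.99 CPM), 122-fold (Kctd15, 21.6 ± 0.425), 118-fold (Smoc2, a matricellular protein gene, 20.9 ± 11), 112-fold (Disp2, 20 ± 10.9, and Gas1, a co-receptor of hedgehog signalling, 19.9 ± 12.6), 101-fold (Cacna1c, a calcium channel gene, 17.9 ± 1.77) and 99.5-fold (Ramp3, 17.7 ± 2.87). Klra15, of a family of near-identical receptors, was at least 145-fold higher and is uncertain. Genes at 0 counts in Tmet were lower by at least 91.2-fold (Cst9), 63.0-fold (Gprin3), 58.2-fold (Arhgef16), 55.1-fold (Zfp385b), 45.3-fold (Vip, a neuropeptide gene) and 44.6-fold (Nr1i2, the pregnane X receptor). The ratios of shControl to Tmet were 1327 (95% counting interval 238 to 52452) for Ildr1 and 1148 (392 to 5569) for Dmbt1, a mucosal glycoprotein gene. Trp53 was called higher (0.94 ± 0.24, adjusted p = 0.0104), but not without shControl replicate 1 or 2 (adjusted p up to 0.0723). Sftpb, a surfactant protein gene, averaged 0.210 CPM against 0.710 (-1.71, adjusted p = 0.0152), a call lost without shControl replicate 1 or 2 or Tmet replicate 2 (adjusted p up to 0.0963) and by DESeq2 (adjusted p = 0.111). Sh3pxd2a (0.33 ± 0.14, adjusted p = 0.0762) and Spp1 (2526 ± 1308 CPM; 1.01 ± 0.42, adjusted p = 0.0703) did not pass.

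Of 29 epithelial genes 23 fell and 2 rose in Tmet (24 and 2 adjusted over the list alone; median -3.66). Camera gave adjusted p = 1.22e-19, and adjusted p = 0.0549 with an estimated correlation. Lsr, of tricellular junctions, fell from 128 to 0.946 CPM (-7.07 ± 0.14, adjusted p = 9.58e-08). Krt7 fell from 116 to 1.13 CPM (-6.68 ± 0.20, adjusted p = 3.33e-07). Stomach and intestine genes fell, 23 of 25 with 1 rising, also adjusted over the list alone (median -6.89, or -6.54 with groups at 0 counts held at their bound; camera adjusted p = 8.86e-32, and adjusted p = 0.0408 with an estimated correlation, so the call held). Lgals4 fell from 838 to 1.80 ± 0.23 CPM (-8.85 ± 0.16, adjusted p = 8.81e-08). Gcnt3, a mucin glycosyltransferase gene, fell from 171 to 0.528 CPM (-8.33). Mesenchymal genes rose, 18 of 24 with 3 falling, also adjusted over the list alone (median 1.40; camera adjusted p = 1.69e-06, and adjusted p = 0.0807 with an estimated correlation). The transcription factor gene Prrx1 rose from 0.651 to 174 ± 6.83 CPM (8.07 ± 0.31, adjusted p = 8.01e-07). Fbn1, fibrillin-1, rose from 0.799 to 263 CPM (8.41 ± 0.37, adjusted p = 1.38e-06), and Twist1 had a ratio of 494 (95% counting interval 169 to 2396). Matrix genes had 20 of 35 higher and 10 lower (22 and 10 adjusted over the list alone; median 1.29; camera adjusted p = 0.000644, and adjusted p = 0.0883 with an estimated correlation). Tnc, tenascin-C, rose from 0.646 to 197 ± 4.97 CPM (8.19 ± 0.23, adjusted p = 2.72e-07). Bgn, biglycan, rose from 9.75 to 2268 ± 404 CPM (7.86 ± 0.23, adjusted p = 2.92e-07). Fibroblast markers rose beside them, 7 of 8 with 1 falling, also adjusted over the list alone (median 4.83; camera adjusted p = 0.000644, and adjusted p = 0.0883 with an estimated correlation). Col1a2, a type I collagen chain, rose from 0.710 to 308 ± 205 CPM (8.77 ± 0.62, adjusted p = 1.55e-05). In Tmet 8 of the 16 fibroblast genes lay over 1 CPM, against 3 in shControl. Of those 16 genes, 6 are also in the matrix list and 1 in the mesenchymal list. Invadopodia genes had 14 of 27 higher and 5 lower (14 and 6 adjusted over the list alone; camera adjusted p = 0.00816, and adjusted p = 0.0883 with an estimated correlation). The cathepsin gene Ctsl rose from 262 to 1064 ± 105 CPM (2.02 ± 0.11, adjusted p = 4.45e-06), and Fscn1 reached 795 ± 142 (2.64 ± 0.17, adjusted p = 1.06e-05).

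Of 32 cell cycle genes 25 rose and none fell in Tmet (28 and 0 adjusted over the list alone; median 1.07). Camera gave adjusted p = 3.15e-05, and adjusted p = 0.52 with an estimated correlation. Mcm7, of the replicative helicase, rose from 163 ± 6.07 to 388 ± 24.4 CPM (1.25 ± 0.12, adjusted p = 9.81e-05). Oncofetal genes had 11 of 16 higher and 4 lower, also adjusted over the list alone (median 2.51; camera adjusted p = 0.0178, and adjusted p = 0.149 with an estimated correlation). Hmga1 rose from 12.5 to 96.7 CPM (2.95 ± 0.17, adjusted p = 5.18e-06). TGF-beta and YAP targets had 14 of 24 higher and 2 lower (14 and 3 adjusted over the list alone; camera adjusted p = 0.0174, and adjusted p = 0.432 with an estimated correlation; call lost without Tmet replicate 2, adjusted p = 0.0672). The inhibitory SMAD gene Smad7 rose from 23.5 to 120 CPM (2.35 ± 0.11, adjusted p = 2.4e-06). Camera did not call hypoxia (8 of 23 higher, 3 lower; adjusted p = 0.119), inflammatory (8 of 17 higher, 2 lower; adjusted p = 0.0943) or RAS-ERK genes (13 of 21 higher, 1 lower; adjusted p = 0.0559), with the same counts adjusted over the list alone. Among them Pgk1, of glycolysis, rose from 620 ± 33.1 to 1823 ± 32.5 CPM (1.56 ± 0.10, adjusted p = 1.09e-05). Ptgs2, of prostaglandin synthesis, rose from 46.0 to 617 ± 154 CPM (3.75 ± 0.30, adjusted p = 2.8e-05), and Spry1, a feedback inhibitor of ERK signalling, fell from 66.8 to 0.603 (-6.77 ± 0.20, adjusted p = 3.02e-07). Interferon (7 of 26 higher, 13 lower; adjusted p = 0.316), Wnt (5 of 9 higher, 4 lower; adjusted p = 0.933) and p53 target genes (5 of 17 higher, 4 lower; adjusted p = 0.991) were not called by camera either. Alveolar genes moved both ways: 4 of 12 type 2 genes rose and 7 fell (camera adjusted p = 0.58) and 4 of 12 type 1 genes rose and 5 fell (camera adjusted p = 0.178). Cldn18, a lung and stomach claudin, fell from 146 ± 4.75 to 0.597 CPM (-7.90 ± 0.21, adjusted p = 1.93e-07). Of 5 airway genes 2 rose and 3 fell, with median -4.26 and mean -0.47 against an upward camera direction (adjusted p = 0.856). Sox2, a transcription factor of airway and stem cells, had a ratio of 1324 (95% counting interval 453 to 6423) at 115 ± 8.53 CPM in Tmet. Xist, the RNA that silences an X chromosome, fell from 1400.2 ± 6.45 to 4.58 ± 0.293 CPM (-8.25 ± 0.17, adjusted p = 9.58e-08), and the Y-linked Ddx3y rose from 0.303 to 107 ± 3.95 (8.49 ± 0.27, adjusted p = 3.64e-07). Of 5 sex-linked transcripts 4 rose and 1 fell (camera adjusted p = 0.000884, and adjusted p = 0.0883 with an estimated correlation). The label check genes were called lower as a list (camera adjusted p = 3.88e-06, and adjusted p = 0.0883 with an estimated correlation). Among lists too small for the test, 1 of 4 liver genes rose and 2 fell, 2 of 4 endothelial genes rose and 1 fell, and 0 of 2 leukocyte genes passed by edgeR (Cd14 29.2 CPM against 28.9). Of 4 neuroendocrine genes 3 rose and 1 fell, the rise of Syp being lost in 7 of the 8 fits that left out 1 library (adjusted p up to 0.18). Of 3 relatives of the targeted genes 3 were called lower, Foxa3 among them at or under the floor in both groups and lost in all 8 such fits (adjusted p up to 0.195).

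**Figure D3:**
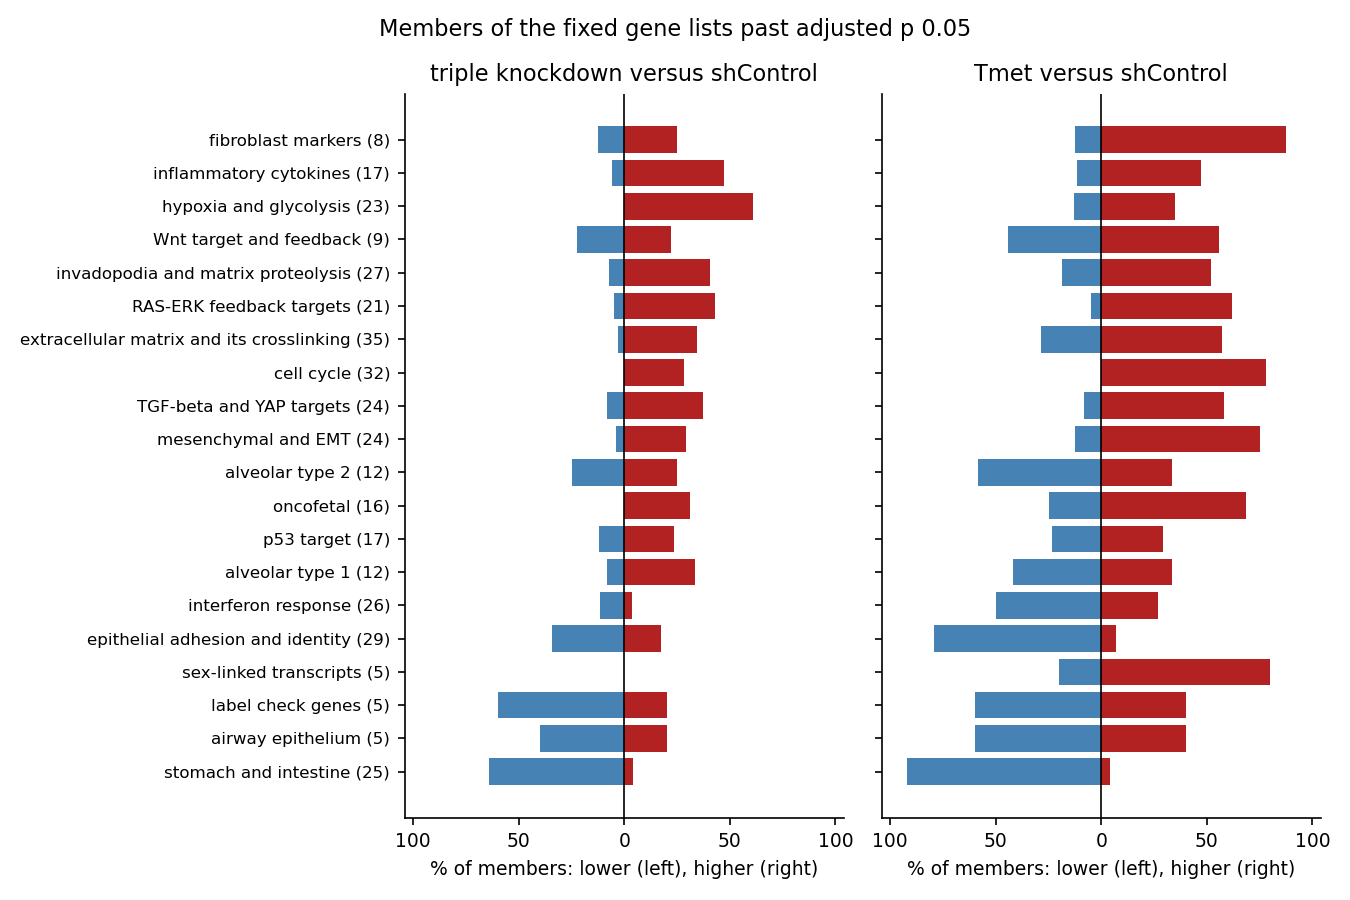
Percent of tested members of each fixed gene list (number tested in brackets) past edgeR's adjusted p of 0.05, lower to the left in blue and higher to the right in red, for the triple knockdown and Tmet, each against shControl. Stomach and intestine genes had 16 of 25 lower in the triple knockdown and 23 of 25 lower in Tmet, while epithelial genes had 10 of 29 and 23 of 29 lower.

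The edgeR test called 7628 genes between Tmet and shControl, 3892 higher and 3736 lower, of which 2048 and 2151 changed more than 2-fold. Without adjustment 8269 passed p 0.05, and the groups did not overlap in 77.2% of tested genes, where chance gives 33.3%. Tmet and Tnonmet lines come from different tumours, so the tumour of origin goes with this comparison. Xist stood at 1274 to 1488 CPM in the Tnonmet libraries and at 4.37 and 4.79 in Tmet. The Y-linked Ddx3y was at most 0.400 CPM in Tnonmet and 105 and 110 in Tmet. This is the pattern of a female and a male source, so sex may also go with every comparison of Tmet. Whether the Tmet lines carry an shRNA is not stated.

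The comparison of Tmet with the triple knockdown tests the difference between those lines directly. Krt7 fell from 1138 ± 38.7 CPM in the triple knockdown to 1.13 ± 0.102 in Tmet (log2 change -9.97 ± 0.22, adjusted p = 1.93e-07). Cdh1 fell from 718 to 3.25 CPM (-7.78 ± 0.17, adjusted p = 1.93e-07). Hnf4a fell from 128 to 0.727 CPM (-7.43 ± 0.22, adjusted p = 4.51e-07). Nkx2-1 (-6.93 ± 0.25, adjusted p = 8.31e-07), Foxa2 (-4.59 ± 0.19, adjusted p = 1.78e-06) and Cdx2 (-4.44 ± 0.26, adjusted p = 8.33e-06) were lower in Tmet, and so was Hmga2 (-0.83 ± 0.17, adjusted p = 0.00494). Trp53 was higher (1.24 ± 0.24, adjusted p = 0.00402), and Vim (0.27, adjusted p = 0.0761; 0.0456 by DESeq2), Foxa1 (0.29, adjusted p = 0.0911), Sh3pxd2a (-0.33, adjusted p = 0.0817) and Spp1 (0.27, adjusted p = 0.626) did not pass. Genes at 0 counts in the triple knockdown were higher in Tmet by at least 233-fold for Krt6a, a keratin of stratified epithelia, 135-fold for Zfp804b, 129-fold for Evc and 126-fold for Slco5a1. Arhgef16 and Kcnk3 had 0 counts in Tmet and were at least 106-fold and 41.7-fold lower, Foxa3 at least 3.95-fold lower. The ratios of triple knockdown to Tmet were 1276 (95% counting interval 229 to 50444) for Galnt3, a mucin glycosyltransferase gene, and 1238 (342 to 10230) for the mast cell tryptase gene Tpsab1.

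Epithelial genes were lower in Tmet than in the triple knockdown, 24 of 29 with 2 higher (24 and 3 adjusted over the list alone; median -2.83), and so were stomach and intestine genes, 18 of 25 with 1 higher (19 and 1 adjusted over the list alone; median -2.75, or -2.39 with groups at 0 counts held at their bound). Camera gave adjusted p = 1.86e-24 and 3.83e-17, and adjusted p = 0.0455 for both with an estimated correlation, so both calls held. Mesenchymal genes were higher, 15 of 24 with 4 lower (18 and 4 adjusted over the list alone; median 1.40; camera adjusted p = 2.1e-05, and adjusted p = 0.072 with an estimated correlation). Prrx1 rose from 0.400 to 174 CPM (8.73 ± 0.33, adjusted p = 1.1e-06). The fibroblast list, beside them, had 6 of 8 higher and 0 lower, also adjusted over the list alone (median 4.08; camera adjusted p = 0.000316, and adjusted p = 0.072 with an estimated correlation). Col1a2 rose from 2.69 to 308 CPM (6.83 ± 0.53, adjusted p = 4.03e-05). Matrix genes went both ways, 18 of 35 higher and 13 lower (camera adjusted p = 0.272). Tnc rose (8.36 ± 0.24, adjusted p = 4.5e-07) and Col6a2, a type VI collagen chain, fell from 97.2 to 3.73 CPM (-4.70 ± 0.18, adjusted p = 1.05e-06). Cell cycle genes were higher, 17 of 32 with 1 lower, also adjusted over the list alone (median 0.58; camera adjusted p = 0.0073, and adjusted p = 0.809 with an estimated correlation), a call lost by fry (adjusted p = 0.0832) and without Tmet replicate 2 (adjusted p = 0.143). Tyms, a thymidylate synthase, rose from 54.2 to 151 CPM (1.47 ± 0.17, adjusted p = 0.000268). Alveolar type 1 genes were lower, 5 of 12 with 1 higher, also adjusted over the list alone (camera adjusted p = 0.00339, and adjusted p = 0.336 with an estimated correlation). Cldn18 fell from 191 to 0.597 CPM (-8.29 ± 0.21, adjusted p = 2.91e-07). Camera did not call hypoxia (2 of 23 higher, 9 lower; adjusted p = 0.285), invadopodia (11 of 27 higher, 5 lower; adjusted p = 0.285) or inflammatory genes (6 of 17 higher, 6 lower; adjusted p = 0.94). Sex-linked transcripts (adjusted p = 0.000136, and adjusted p = 0.072 with an estimated correlation) and label check genes (adjusted p = 3.57e-05, and adjusted p = 0.128 with an estimated correlation) were called by camera, higher and lower. Median, mean and camera direction differed in sign for airway, inflammatory and Wnt genes, none of them past its test.

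The edgeR test called 6404 genes between Tmet and the triple knockdown, 3191 higher and 3213 lower, of which 1577 and 1681 changed more than 2-fold. Without adjustment 7353 passed p 0.05, and the groups did not overlap in 72.1% of tested genes, where chance gives 33.3%. In a fit of the 4 libraries compared the count was 4413. The count was 3962 without triple knockdown replicate 2. Over the 5 comparisons camera called 41 lists, of which 4 held with an estimated correlation.

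The changes of the triple knockdown and of Tmet were set side by side. Triple knockdown against shNkx2-1 and Tmet against shControl share no library, and 1749 genes were called in the same direction in both: 720 higher, where independent lists would share 361, and 1029 lower, where they would share 414 (Fisher's exact p = 3.36e-111 and 6.38e-277, across genes, which are not independent). Another 314 genes were called in opposite directions. Of the genes the triple knockdown raised over shNkx2-1, 58.3% were higher in Tmet, and of those it lowered, 69.7% were lower in Tmet. Fold changes correlated across genes at r = 0.373 (Spearman's rho 0.411, covariance 0.965). The shared count was 1057 and 757 without shNkx2-1 replicate 1 or 2, 820 and 774 without triple knockdown replicate 1 or 2, and 3200 and 2883 without Tmet replicate 1 or 2.

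With shControl as the base of both, 2182 genes were called in the same direction, 969 higher and 1213 lower, where independent lists would share 467 and 462, and 318 in opposite directions. Fold changes correlated at r = 0.522 (rho 0.495) with a covariance of 1.46. Over 100 simulations of unchanged groups against shared controls, which were simulated too, r averaged 0.501 (0.431 to 0.555) and rho 0.463 (0.434 to 0.480). The range of r holds the observed r, and that of rho lies below the observed rho. Unchanged groups that share controls give such an r from noise alone, so r does not decide whether the changes agree. The covariance averaged 0.0970 (0.0805 to 0.119) and the shared calls 0.05 (0 to 1). The observed covariance exceeded the simulated one by 1.37. The 2 shControl libraries were not split between the comparisons, which would leave 1 control library for each, so part of the excess of shared calls may come from the shared controls. Of the shared genes 895 lay further from shControl in Tmet and 153 further in the triple knockdown by the direct test. The genes named next were chosen after their values were seen. Pkp1, a desmosomal plakophilin, rose in both (0.52 CPM in shControl, 27.1 in the triple knockdown, 81.9 in Tmet; log2 changes 5.61 ± 0.45 and 7.21 ± 0.45), and Cyp4f14 and Gdf6 fell in both. Krt7 rose in the triple knockdown and fell in Tmet, as did Mpzl2, a junctional adhesion gene (8.37, 52.0 and 0.13 CPM; 2.63 ± 0.17 and -5.93 ± 0.29), while Gpr149 fell in the triple knockdown and rose in Tmet (2.95, 0.124 and 49.3 CPM; -4.48 ± 0.42 and 4.07 ± 0.24). The shared count was 907 and 1159 without shControl replicate 1 or 2, 1060 and 1076 without triple knockdown replicate 1 or 2, and 3539 and 3322 without Tmet replicate 1 or 2.

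**Figure D4:**
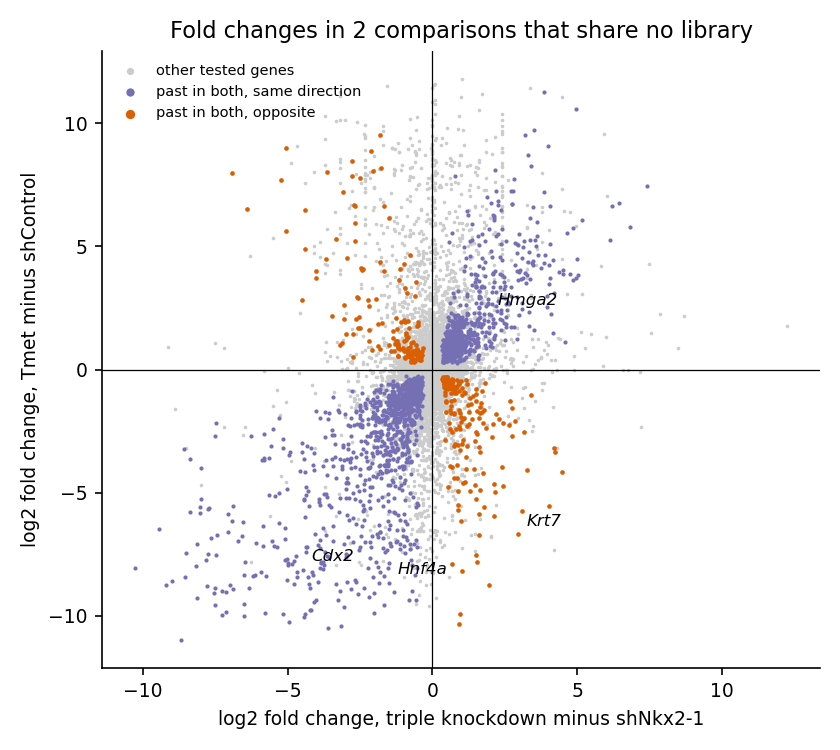
Log2 fold change of each tested gene in the triple knockdown minus shNkx2-1 (x axis) and in Tmet minus shControl (y axis), which share no library; each point is 1 gene. The 1749 genes past both tests in the same direction lie in the upper right (720) and lower left (1029), among them Hmga2, Cdx2 and Hnf4a, and the 314 past both in opposite directions include Krt7.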

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

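The fit without both Tmet libraries, and all alternatives for the calls shared by the comparisons against shControl, were chosen after seeing the data. No called direction turned round under any alternative. The count of genes called between shNkx2-1 and shControl, 473, moved most: 1779 in a fit of the 4 libraries compared, 294 with a replicate block, 908 by DESeq2, 22 by glmTreat against a 2-fold change, 2006 without both Tmet libraries, and 0 to 1998 when leaving out 1 library. For triple knockdown against shControl, 3243 became 5607 in a fit of the 4 libraries compared, 719 by glmTreat, 5424 without both Tmet libraries and 1248 to 5459 when leaving out 1 library. For triple knockdown against shNkx2-1, 2711 became 4518, 566, 4958 and 1024 to 4994 in the same order. Tmet against shControl (7628) gave 2726 by glmTreat and 5534 to 8882 when leaving out 1 library, and Tmet against triple knockdown (6404) gave 1982 and 3962 to 7901. The 1749 and 2182 shared calls ranged from 757 to 3200 and from 907 to 3539 when leaving out 1 library; glmTreat was not run for them. In a fit of the 4 libraries compared, Tmet against shControl gave 5944 calls and Tmet against triple knockdown 4413, both fewer than in the reported fit. glmTreat tests for a change beyond 2-fold, and so calls fewer genes by construction. The fit without Tmet estimates the spread from the Tnonmet libraries alone, whose duplicates were closer. For the other moves the cause was not tested. A fit without 1 library assumes that the library left alone in its group varies like the other groups. DESeq2 size factors, both filters, limma-voom and counts not rounded kept every count within 1.5 times. Replicate numbers are shared between the titles, but nothing says that a number marks a shared culture or day: deviations of same-numbered libraries correlated at 0.27, 0.27 and 0.37 among the Tnonmet groups and at -0.06, -0.23 and -0.28 with Tmet, and 6 of 8 libraries matched best a library of their own number. The 2 libraries of a group deviate from its mean in mirror image, so these 8 matches count each group 2 times. The correlations are a hint from the data of pairing among the Tnonmet groups, which the design does not give and Tmet does not share. With only 2 numbers per group, the numbers were not taken as pairs. With the replicate block the other counts were 2951, 2389, 7351 and 6062, and the shared calls 1559 and 1994. Among the calls that the block ended were those of Nkx2-1 (adjusted p = 0.0619) and Cdx2 (adjusted p = 0.0629) between shNkx2-1 and shControl. Among lists it ended the camera calls of oncofetal genes in shNkx2-1 (adjusted p = 0.0742) and in the triple knockdown (adjusted p = 0.172), each against shControl. It also ended those of alveolar type 1 genes (adjusted p = 0.172) and label check genes (adjusted p = 0.0615) in the triple knockdown against shControl, and of label check genes against shNkx2-1 (adjusted p = 0.265). It added a call of RAS-ERK targets in Tmet against shControl (adjusted p = 0.0277) and calls of Sh3pxd2a in the triple knockdown against shNkx2-1 (adjusted p = 0.0254), in Tmet against shControl (adjusted p = 0.0277) and in Tmet against the triple knockdown (adjusted p = 0.0285). Of 428 calls of named genes, 428 were kept with counts not rounded, 427 with DESeq2 size factors, 424 without a filter, 423 by limma-voom, 421 by DESeq2, 415 with the replicate block, 285 by glmTreat, 379 of 380 with the filter of 5 CPM, 419 of 425 in fits of 4 libraries, 214 of 214 without both Tmet libraries, and 361 to 424 when leaving out 1 library. Of 41 list calls by camera, 41 were kept with DESeq2 size factors, 36 by fry, 36 with the replicate block, 33 to 41 when leaving out 1 library and 4 with an estimated correlation. The calls that fry ended were those of TGF-beta and YAP targets (adjusted p = 0.125) and oncofetal genes (adjusted p = 0.0586) in shNkx2-1 against shControl, and of cell cycle genes in the triple knockdown against shControl (adjusted p = 0.127) and shNkx2-1 (adjusted p = 0.0735) and in Tmet against the triple knockdown (adjusted p = 0.0832). Fry, which does not compare a list with other genes, called 2, 13, 9, 16 and 11 lists in 1 direction over the comparisons in the order shNkx2-1 against shControl, triple knockdown against shControl, triple knockdown against shNkx2-1, Tmet against shControl and Tmet against triple knockdown, and 16, 19, 19, 20 and 20 in either direction. Depth limits what was seen below 0.151 to 0.2 CPM, and in the simulation of triple knockdown against shControl 8.96% of genes changed 1.5-fold were recovered, against 95.5% of those changed 4-fold.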

Other observations

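Both gene groups described first, and the tests of Amd1 and of mixed fibroblasts, were chosen after their results were seen; the chromosome tests were written before their results, once shifts of chromosome medians had been noticed in the same data. Several other gene families were looked over before these 2 groups were picked, and the camera adjustment covers only their 10 tests. Brush border genes, which build the microvilli of absorptive epithelium, fell with the 3 shRNAs: 12 of 16 tested fell and 1 rose against shControl (median log2 change -1.62; camera adjusted p = 5.06e-25, and adjusted p = 0.00665 with an estimated correlation), and 12 fell and 2 rose against shNkx2-1 (median -2.56; adjusted p = 8.21e-29, and adjusted p = 0.00665 with an estimated correlation). Vil1, also in the fixed intestinal list, is 1 of them. The protocadherin gene Cdhr5 went from 185 ± 14.9 CPM in shControl to 4.80 in the triple knockdown (-5.27 ± 0.17, edgeR adjusted p = 3.25e-06) and 0.185 in Tmet (-9.92 ± 0.24), and the myosin gene Myo7b from 198 ± 4.87 to 8.22 (-4.59 ± 0.12, edgeR adjusted p = 1.67e-06) and 0.916, while in shNkx2-1 they stood at 174 and 282 CPM. In Tmet against shControl 13 of 16 fell and 3 rose (median -6.20; adjusted p = 2.74e-15, and adjusted p = 0.0141 with an estimated correlation). In shNkx2-1 against shControl 2 rose and none fell (median -0.06, mean 0.15; camera adjusted p = 0.582). Between Tmet and the triple knockdown 9 were lower and 2 higher (adjusted p = 0.000294, and adjusted p = 0.115 with an estimated correlation).

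Genes of fatty acid oxidation and ketone body synthesis were lower in the triple knockdown against shControl, where 8 of 24 fell and none rose (median -0.39, camera adjusted p = 0.000177, and adjusted p = 0.42 with an estimated correlation). In Tmet against shControl 17 fell and 1 rose (median -1.14, camera adjusted p = 0.000107, and adjusted p = 0.42 with an estimated correlation). Hadha, of the oxidation cycle itself, stood at 292 CPM in shControl, 300 in shNkx2-1, 188 in the triple knockdown and 115 in Tmet (-0.64 ± 0.09 in the triple knockdown and -1.34 ± 0.10 in Tmet, edgeR adjusted p = 0.00256 and 1.68e-05). The Wnt ligand gene Wnt7b lies outside both groups and was also chosen after its values were seen. It went from 2.73 ± 0.743 CPM in shControl to 153 ± 12.5 in the triple knockdown (5.79 ± 0.54, edgeR adjusted p = 0.000313) and 45.3 ± 31.4 in Tmet (4.03 ± 0.52, edgeR adjusted p = 0.00038).

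Genes shifted chromosome by chromosome in Tmet against shControl. Over 6998 autosomal genes above 20 CPM, assigned to the 19 autosomes by the GRCm38.p6 annotation, the autosome medians had an SD of 0.326, where 1000 shuffles of genes gave up to 0.0661 at the top of their 95% range; the medians were 0.79 for chromosome 18, 0.58 for chromosome 13, -0.41 for chromosome 10 and -0.38 for chromosome 9. A regression on GC content and transcript length left an SD of 0.312, which argues against either bias as the whole cause, and replicates 1 and 2 taken alone gave medians that correlated at r = 0.982, which argues against 1 deviating library. Far smaller shifts stood above the highest of 1000 shuffles between groups of the same Tnonmet tumour too: an SD of 0.0393 against 0.0238 for shNkx2-1 against shControl, and 0.0432 against 0.0407 for the triple knockdown against shNkx2-1, while the triple knockdown against shControl gave 0.0391, above the top of the 95% range of its shuffles (0.0352) and below their highest (0.0397). Their cause was not tested. For Tmet against shControl, the medians of the first and second parts of each chromosome in gene order correlated at r = 0.93 (rho 0.916, permutation p = 1e-05, the smallest that 100000 permutations give). The shifts thus ran along whole chromosomes. DNA copy number that differs between the lines is a candidate explanation. Any chromosome-wide cause would make the parts correlate, so this test does not single it out. Regulation that acts on whole chromosomes stays open, since no DNA was measured.

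Camera with its preset correlation called mesenchymal, matrix and fibroblast genes higher and epithelial genes lower in Tmet against shControl, though some matrix genes fell. With an estimated correlation these list calls were lost. Fibroblasts mixed into a culture otherwise like shControl could give such a pattern. Such a mixture dilutes alike all epithelial genes that fibroblasts do not express. The log2 changes of the 16 epithelial genes above 10 CPM in shControl had an SD of 2.77, against a root mean square SE of 0.275. Krt18 kept 61.1% of its shControl level and Pkp2 35.1%, while Cdh1 kept 0.333% and Elf3 0.28%. Because no fibroblasts were measured, it is not known whether they express the genes that kept more. The spread alone therefore does not decide about that mixture. However, 6 of the 16 genes kept under 1% of their shControl level, while 7 kept over 10%. A mixture could leave so little of those 6 only if cells like shControl gave under 1% of the RNA. These values argue against a culture made mainly of cells like shControl. A smaller share of fibroblasts in a culture of other tumour cells stays open: Col1a1 stood at 209 ± 193 and Col1a2 at 308 ± 205 CPM in Tmet, with Pdgfra at 1.61. So do a mesenchymal state of the tumour cells and the tumour of origin, which the design does not separate.

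Amd1 had 0 counts in the 4 libraries with an shRNA against Nkx2-1, 352 estimated counts in each of shControl 1, shControl 2 and Tmet 1, and 705 in Tmet 2, while its copy Amd2 stood at 100.3 CPM in shControl, 103 in shNkx2-1 and 94.2 in the triple knockdown. Equal counts in libraries whose totals ran from 14496995 to 18918538 do not follow depth, as reads of an expressed gene would, so the values of Amd1 are not read as levels. Reads moved from Amd1 to Amd2 could give this, and would leave their sum as it was. The sum changed by -0.30 (SE 0.196) on the log2 scale, and loss of the Amd1 part alone would give -0.27, so the value lies near the loss but less than 2 SE from no change. The sum therefore does not decide whether the Amd1 transcript changed at all.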
